A study of Homo sapiens with 6 samples.

How the data were processed

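Methylation of ribosomal RNA was measured by RiboMethSeq in Kasumi-1, an established acute myeloid leukaemia cell line that carries the RUNX1-RUNX1T1 fusion. The labels name 3 libraries from cells with a knockout of SNORD42A, a box C/D small nucleolar RNA (snoRNA) that guides methylation of ribosomal RNA, and 3 libraries of control cells named CTRL_KO. The method reads 2'-O-methylation from the protection it gives: alkali does not cut the bond next to a methylated ribose, so few fragments begin or end there. Per the labels' protocols, 100 ng of total RNA per library was hydrolysed for 12 min at 95 °C to fragments near 30 nucleotides, which entered a small RNA library kit.

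The authors deposited a table of counts and a table of scores for all 6 libraries. The deposited counts are whole numbers of read ends at each of 7000 rRNA positions (1836 of 18S, 5021 of 28S and 143 of 5.8S) and carry no normalization. Trim Galore and Bowtie2 are named for trimming and alignment, without versions, per the submitters' processing notes. The rRNA reference, the counting rule and the treatment of multiply aligned reads are not given in the sources used here, and positions keep the numbering of the files. The deposited score C covers 95 listed sites (35 in 18S, 58 in 28S and 2 in 5.8S) with the guide snoRNA the authors list for each. All 95 scores were rebuilt from the deposited counts in every library, with a largest difference of 5.55e-16, as 1 minus the count at the next position divided by the mean of its flanks. The flanks are 6 positions on each side with weights from 1 at the nearest to 0.5 at the farthest. A score near 1 is thus full protection, and 1 minus the score, given here as a percentage, is the remainder of read ends relative to the flanks. The score is relative to neighbouring positions, so a modification next to a site or a sequence that is cut unevenly moves it, and it is not a molar fraction of methylated ribosomes. A smooth change of coverage along the rRNA cancels from the score but not from the plain counts.

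Libraries held between 16229300 and 17317900 read ends, with a median of 327.5 to 399 per position. The mean flank count at the listed sites had a median of 1510 and a minimum of 167. For 18S-Um116, 95% exact Poisson intervals of the read ends were carried to the score with the flanks held fixed. They cover counting error only, since PCR copies without molecular identifiers are not independent molecules. No pair of libraries was as alike as repeat counts of 1 library would be: the chi-square per degree of freedom over positions was at least 4.85 for all pairs, so each library was counted as 1 sample. The most alike pair crossed the genotypes (knockout replicate 1 and control replicate 2). The lowest value within a genotype was 10.5, for knockout replicates 1 and 3. The labels do not say whether replicates are separate cultures or clones, and p-values measure the spread between these libraries, which may be technical in part.

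Scores were compared between genotypes with limma 3.58.1 in R 4.3.3, untransformed, with eBayes moderation and Benjamini-Hochberg adjustment over the 95 sites at a threshold of 0.05. Per-library values were compared with two-sided exact permutation tests, whose smallest p with 3 against 3 libraries is 0.1. Lists of sites were tested with camera at a preset correlation of 0.01, with camera's estimated correlation and fry beside it. The lists were the 18S, 28S and 5.8S sites, the sites of guides encoded in RPL23A, 18S sites within 100 nucleotides of Um116, partly methylated sites with a mean score below 0.8, highly methylated sites at or above it, and sites with or without a listed neighbour within 6 nucleotides. Um116 stayed out of every list but that of RPL23A-encoded guides. Planned lists by modified base were not run, because the base at each position is not given in the sources used here. The names Um116 and Um121 come from the known targets of the guides, and the files give the numbers and guides only. Read-end counts were tested at every position with a mean count of at least 10 by edgeR 4.0.16 (TMM normalization, quasi-likelihood test). The same test with the log of the flank mean as an offset, at positions with a mean flank count of at least 50, tested read ends relative to their flanks. Score C was also recomputed at every position with that flank minimum, with a floor at 0, and compared with limma. Standard errors of edgeR fold changes are the log2 fold change divided by the square root of its F statistic. Neighbouring positions share fragments and are not independent.

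Apart from members of the partly methylated list and sites named after their values were seen, the sites named in the text follow a rule fixed before the data were examined: Um116, Um121, the other 18S sites within 100 nucleotides of Um116, both 5.8S sites, up to 12 sites of each direction past the threshold, the 4 largest rises and falls of the score, the 3 lowest mean scores, and the 5 positions of each direction with the smallest p in each test over positions. The lists, tests and most alternatives were fixed then too. The alternatives were the logit and arcsine scales, trended and robust moderation, centring, other flank widths and depth minimums, other normalizations, the DESeq2 1.42.0 Wald test, the replicate number as a block, and each library left out in turn. Library weights, leaving out both libraries that stand apart, and adjustment of the count and flank tests over the listed sites alone were chosen after seeing the data.

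The main tests were tried on simulated data with known answers for this comparison, while fry, DESeq2 and camera with an estimated correlation were not. Counts were drawn independently at each position from the real means, dispersions and library sizes, with 200 changed positions. The edgeR count test (6497 positions) found 46.3% of changes of 0.5 on the log2 scale, 97.0% of changes of 1 and 100% of changes of 2. With flank offsets (5817 positions) the shares were 43.9%, 95.5% and 100%, and with limma on the recomputed score (5871 positions) 3.03%, 23.9% and 66.7%. False calls numbered 11 by counts, 74 relative to flanks (12 of them beyond the flanks of changed positions) and 14 by the recomputed score. The simulated counts lacked the shared fragments and library-wide differences of the real libraries. These shares can therefore overstate the power of the real tests, above all for 1 changed position. Scores were drawn independently at the 95 sites from each site's own mean and SD, with 200 sites lowered by each step over 50 draws. Limma found 77.5% of sites lowered by 0.05, 89% of those lowered by 0.1 and 97.5% of those lowered by 0.2, with 35 false calls. Several sites changed together in each draw and no library stood apart, so these shares can overstate the power for 1 changed site here. Camera called a simulated fall of 0.1 at the partly methylated sites in 50 of 50 draws, and 4.22% of unchanged lists had an unadjusted p under 0.05. The real difference of that list was smaller in size (-0.043), so the power for it was not measured. Sites in these draws were independent, so neither share covers correlation between sites. Gene names and neighbours come from a RefSeq gene table of GRCh38.p14, and no genome coordinates are printed because the files name no build. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.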

Results

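The data covered 2'-O-methylation of the 18S, 28S and 5.8S rRNA in Kasumi-1 cells of 2 genotypes, SNORD42A_KO and CTRL_KO, with 3 libraries each. The comparison asks how methylation of rRNA differs when SNORD42A is knocked out. Knockout libraries held 17217000, 16229300 and 16415600 read ends for replicates 1, 2 and 3, and control libraries 17245900, 17317900 and 17218300. In these deep libraries most sites were close to fully protected: 81 of the 95 listed sites had a mean score C of at least 0.9 in the controls. On the first principal component of the log counts, which held 47.0% of the variance, knockout replicate 2 (-17.6) and control replicate 3 (20.8) stood apart from the other libraries (-3.28 to 2.90). Control replicate 3 also gave 26.9% of its read ends to 18S, against 21.2% to 23.1% in the other libraries.

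18S-Um116, the small-subunit site listed for SNORD42A and its paralogue SNORD42B, had a lower score C in each of the 3 knockout libraries than in any control library. Its mean score was 0.823 ± 0.115 (SD, n = 3) in the knockout and 0.937 ± 0.0056 (SD, n = 3) in the control. The knockout libraries scored 0.885, 0.690 and 0.894, and the control libraries 0.932, 0.935 and 0.943. Relative to its flanks, the remainder of read ends at the site was 17.7% ± 11.5 (SD, n = 3) in the knockout and 6.35% ± 0.556 (SD, n = 3) in the control, a ratio of 2.79. The site was far from unprotected even in knockout replicate 2, where 12.9% of the 5766 unlisted positions reached its score, with a median score of 0.138 over those positions.

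By counts, 517, 1450 and 531 read ends reported the target nucleotide in the knockout libraries and 314, 299 and 300 in the controls, which is 50.6 ± 33.6 (SD, n = 3) and 17.6 ± 0.504 (SD, n = 3) as a share of the library (CPM). Mean flank counts were nearly equal, at 4731 in the knockout and 4812 in the control. The 95% Poisson interval of the score was 0.674 to 0.706 in knockout replicate 2, while the other 2 knockout libraries lay between 0.874 and 0.903 and the controls between 0.924 and 0.949. In limma the difference was -0.113 ± 0.0581 (SE), the largest of the 95 sites in size with all libraries and the deposited score, with an adjusted p = 0.626. An exact permutation test gave p = 0.1, the smallest value the design allows. For read ends, edgeR gave a log2 fold change of 1.57 ± 0.36 (SE) with an adjusted p = 0.354, and 1.48 ± 0.36 (SE) relative to the flanks with an adjusted p = 0.503. Adjusted over the list alone (77 listed sites with enough counts, an adjustment chosen after seeing the data), the values were adjusted p = 0.0696 and adjusted p = 0.0649. Um116 was fixed as the target in advance. Unadjusted, its p was 0.105 by limma, 0.000967 by the edgeR count test and 0.00183 by the edgeR test relative to the flanks. Unadjusted p-values under 0.05 were frequent over all positions in these edgeR tests, at 13.5% and 9.67%. After adjustment the site passed no threshold in these fits, although its scores did not overlap between genotypes.

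Knockout replicate 2 set much of the size and of the spread at Um116. Without it the score difference was -0.047, smaller in size than that of 18S-1447 (-0.052), the ratio of remainders was 1.74, and the flank test adjusted over the list alone gave a log2 fold change of 0.80 ± 0.092 (SE) with an adjusted p = 0.000904. Adjusted over all positions, the site did not pass without knockout replicate 2 in the flank test (adjusted p = 0.0681) or the count test (adjusted p = 0.191). Limma on the score gave an adjusted p = 0.0603 there. The flank test over the list alone also passed without knockout replicate 3, at an adjusted p = 0.00668, but not without knockout replicate 1 (0.0516) or control replicates 1, 2 or 3 (0.148, 0.115 and 0.148). With knockout replicate 2 and control replicate 3 both left out, a choice made after seeing the data, the edgeR count test over all positions gave a log2 fold change of 0.80 with an adjusted p = 0.0489. The flank test over all positions did not pass there (adjusted p = 0.190), nor did limma on the score (adjusted p = 0.199).

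**Figure D1:**
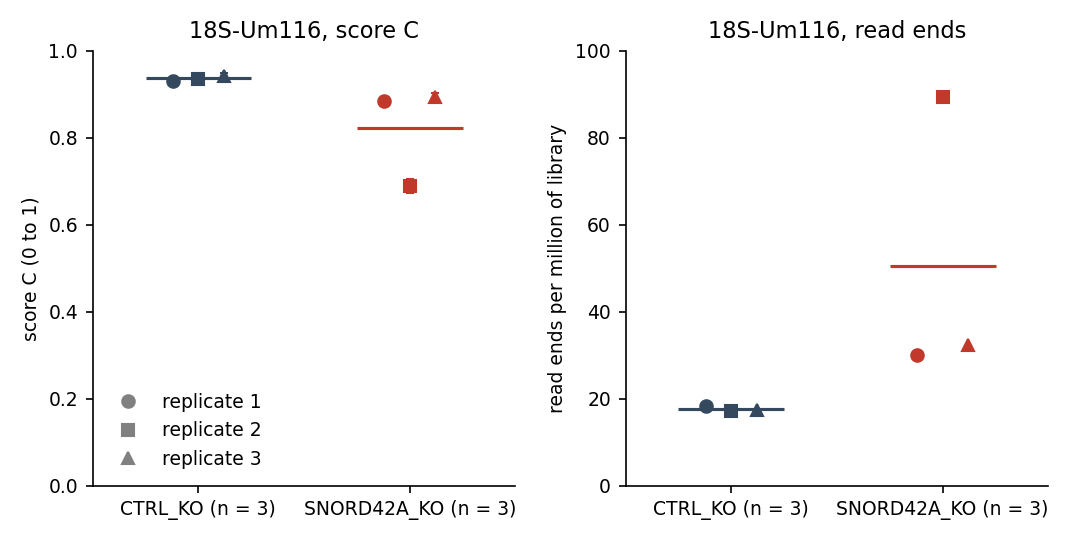
Score C (left, 0 to 1) and read ends as CPM (right) at 18S-Um116 for each CTRL_KO and SNORD42A_KO library, with horizontal lines at the group means and bars on the scores for 95% Poisson counting intervals, mostly hidden by the symbols. The 3 control libraries sit between 0.932 and 0.943, knockout replicates 1 and 3 at 0.885 and 0.894, and knockout replicate 2 at 0.690.

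Score differences at the other methylated 18S nucleotides near the target were small, the largest in size being -0.013 at 18S-27. 18S-Um121 is guided by SNORD4A and SNORD4B, which lie with SNORD42A and SNORD42B inside the ribosomal protein gene RPL23A on chromosome 17, where the order is SNORD42B, SNORD4A, SNORD42A and SNORD4B. Its score was 0.959 ± 0.0046 (SD, n = 3) in the knockout and 0.964 ± 0.0045 (SD, n = 3) in the control, a difference of -0.0051 with a 95% interval of -0.015 to 0.0048. 18S-27, the site of SNORD27, scored 0.955 ± 0.0053 (SD, n = 3) in the knockout and 0.968 ± 0.0075 (SD, n = 3) in the control, and the ranges did not overlap. The 95% interval of this difference was -0.026 to -0.00035, with a limma adjusted p = 0.490. 18S-99 (SNORD57) differed by 0.0033, 18S-159 (SNORD45C and SNORD45A) by -0.0018, 18S-166 (SNORD44) by 2.93e-06 and 18S-172 (SNORD45B) by -0.0029. These small values moved with single libraries: to -0.0028 at Um121 and -0.00021 at 18S-172 without control replicate 2, to 0.0103 at 18S-99, 0.0040 at 18S-159 and -0.0011 at 18S-166 without knockout replicate 2, and to -0.0017 at 18S-99 without knockout replicate 3. Of these 6 sites within 100 nucleotides of the target, 4 were lower and 2 higher in the knockout, none past the threshold, and the list had an adjusted p = 0.831 by camera, with a mean difference of -0.0033 that was -0.00077 without knockout replicate 2. The RPL23A-encoded guides, Um116 and Um121 together, were both lower in the knockout, with a list adjusted p = 0.450, and 0.697 with an estimated correlation. Without knockout replicate 2 the list difference went from -0.059 to -0.025 and its adjusted p to 0.0427, and most of that difference was Um116 itself (-0.047).

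**Figure D2:**
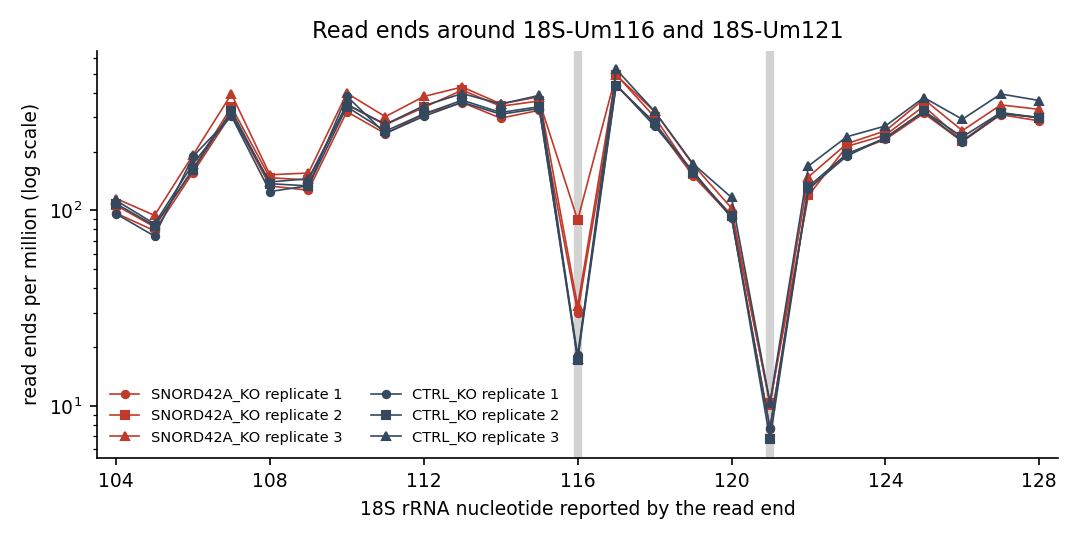
Read ends as CPM (log axis) at the 18S nucleotides around Um116 and Um121, which are marked by grey bands, with 1 line per library. The 6 libraries run close together except at Um116, where the controls lie at 17.3 to 18.2 CPM and the knockout libraries at 30.0, 89.3 and 32.3.

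Across all 95 listed sites, 59 had a lower and 36 a higher mean score in the knockout, and the median size of the difference was 0.0065. After Um116, the lowest differences belonged to 28S-4020, the site of SNORD102 (-0.057, from 0.757 in the control to 0.700), 28S-4560 of SNORD119 (-0.048) and 18S-1447 of SNORD127 (-0.047, from 0.521 to 0.474). The highest were 28S-3723 of SNORD87 (0.049), 18S-627 of SNORD65 (0.032), 28S-2774 of SNORD99 (0.031) and 28S-1303 of SNORD21 (0.029). Scores at 28S-4020 and 18S-1447 did not overlap between genotypes, while at 28S-3723 the control spread (SD 0.093, n = 3) was larger than the difference. The gaps were narrow. The highest knockout and lowest control scores were 0.746 and 0.748 at 28S-4020, and 0.484 and 0.489 at 18S-1447. With 1 library left out the difference ran from -0.080 to -0.038 at 28S-4020 and from -0.063 to -0.036 at 18S-1447. The 28S-4560 value came from control replicate 3, which scored 0.692 against 0.527 and 0.529 in the other controls. Without that library the difference was 0.0069, and without control replicate 2 that at 28S-3723 was -0.0029. Without knockout replicate 1 the difference was 0.020 at 18S-627 and 0.013 at 28S-2774, and without knockout replicate 2 it was 0.018 at 28S-1303.

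No site passed the threshold in limma, where the lowest adjusted p was 0.490 and 9 sites had an unadjusted p under 0.05, of which 8 were lower in the knockout. These 9 were 28S-2848, 28S-4590, 28S-4426, 18S-1447, 28S-4593, 28S-391, 18S-683, 18S-27 and 28S-4020, of which 28S-391, a site of SNORD81, was the higher one, and all but 18S-27, 18S-1447 and 28S-4020 were named here after their values were seen. At 17 sites (17.9%) the 3 knockout and 3 control scores did not overlap, against 10% by chance, and 13 of these were lower in the knockout. The median SD was 0.0052 among controls and 0.0082 among knockouts. By the flank test, 14 of 77 listed sites had an unadjusted p under 0.05, 11 of them toward less protection in the knockout, and 0 passed when adjusted over the list alone. That count was 7 without knockout replicate 3, 1 without knockout replicate 2 and 1 without control replicate 1. The mean score of all sites but Um116 was 0.936 ± 0.0056 (SD, n = 3) in the knockout and 0.940 ± 0.0032 (SD, n = 3) in the control, with an exact permutation p = 0.4, and the difference went from -0.0038 to -0.00058 without knockout replicate 2.

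**Figure D3:**
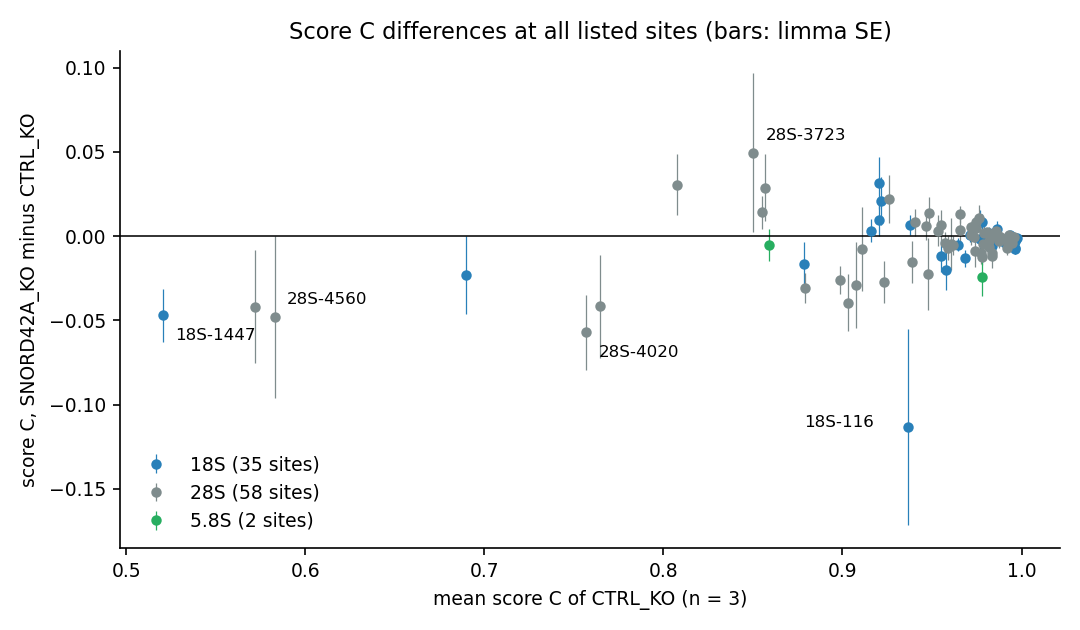
Difference of mean score C, SNORD42A_KO minus CTRL_KO, against the mean score of the control for the 95 listed sites, coloured by rRNA, with bars of 1 standard error from limma. 18S-116 lies lowest at -0.113, and the sites with a control mean below 0.8 all lie below 0.

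The partly methylated sites, 6 sites with a mean score below 0.8, were all lower in the knockout. No other limit was tried, and sites just above it went both ways. Differences were 0.031 at 28S-2774 (mean score 0.823) and 0.014 at 28S-4362 (0.862). They were -0.0055 at 5.8S-14 (0.856) and -0.031 at 28S-2848 (0.864). The mean of the partly methylated sites was 0.605 ± 0.018 (SD, n = 3) in the knockout and 0.648 ± 0.029 (SD, n = 3) in the control, a difference of -0.043, with an exact permutation p = 0.1. The 6 sites include 3 of the sites with the lowest scores of all, 18S-1447, 28S-4588 (SNORD91B and SNORD91A, 0.530 in the knockout and 0.572 in the control) and 28S-4560. The others were 28S-4020, 28S-2863 of SNORD50A and 18S-1272 of SNORD66. Camera gave the list an adjusted p = 0.0515, and an adjusted p = 0.560 with an estimated correlation. Without control replicate 3, the library with the high 18S share, the difference was -0.028 with an adjusted p = 0.499, with 28S-4588 going from -0.042 to -0.016, and without control replicate 2 it was -0.057 with an adjusted p = 0.00468. The list also passed without knockout replicate 1, at an adjusted p = 0.0452, but not without knockout replicate 2 (0.0800), knockout replicate 3 (0.0750) or control replicate 1 (0.0859).

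Among the 88 highly methylated sites, 52 were lower and 36 higher in the knockout, with a mean difference of -0.0011. This list passed camera with an adjusted p = 0.0432. Camera tests a list relative to the other sites, here only the 6 partly methylated sites and Um116, which were lower still. The call thus mirrors their falls and is no separate result. It was lost with an adjusted p = 0.560 with an estimated correlation, and also without control replicate 3 (adjusted p = 0.499), control replicate 1 (adjusted p = 0.0816) or knockout replicate 3 (adjusted p = 0.0603). Without knockout replicate 2 the mean difference of the highly methylated list was 0.0016, of the other sign, and the list still passed camera (adjusted p = 0.0104). The 34 18S sites other than Um116 (21 lower, mean difference -0.0021, camera adjusted p = 0.880) and the 58 28S sites (35 lower, -0.0044, adjusted p = 0.880) gave no call. Both 5.8S sites were lower in the knockout, 5.8S-14 of SNORD71 by -0.0055 and 5.8S-75 of SNORD96A and SNORD96B by -0.024, the latter without overlap, and their list had an adjusted p = 0.563. Without knockout replicate 2 the difference at 5.8S-75 was -0.013, and without control replicate 1 that at 5.8S-14 was 0.00047. Sites with a listed neighbour (29, mean difference -0.0045) and without one (65, -0.0035) had a camera adjusted p = 0.880 each. Without knockout replicate 2 these became -0.0018 and -5.47e-05, and the 18S and 28S lists both -0.00031.

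**Figure D4:**
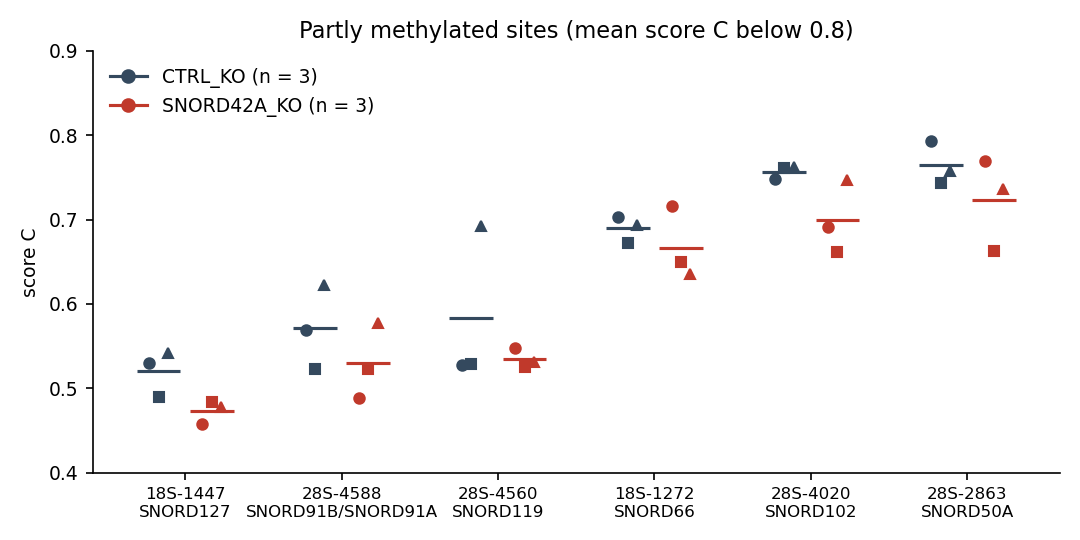
Score C of each library at the 6 partly methylated sites, CTRL_KO beside SNORD42A_KO, with horizontal lines at the group means, symbols for the replicate number (circle 1, square 2, triangle 3) and an axis that starts at 0.4. Group means are lower in the knockout at all 6 sites, and the libraries overlap except at 18S-1447 and 28S-4020.

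Beyond the listed sites, no rRNA position passed the threshold in any of the tests over positions. Of 6496 positions tested for read-end counts, 877 had an unadjusted p under 0.05 in edgeR (13.5%), and the lowest adjusted p was 0.354. DESeq2 also gave 0 positions, with 712 at an unadjusted p under 0.05. The 5 positions with more read ends and the smallest p were 28S-2301, 18S-116, 28S-3850, 28S-3527 and 28S-1439, with log2 fold changes of 0.46 to 1.57. By p, Um116 ranked 2 in this edgeR test, 99 in DESeq2, 12 relative to the flanks and 832 by the recomputed score. The 5 with fewer were 18S-1798, 5.8S-34, 18S-1618, 18S-362 and 5.8S-50, with log2 fold changes of -0.86 to -0.55, of which 5.8S-34 and 5.8S-50 (-0.55 each) were at -0.24 when each rRNA was normalized on its own. Without knockout replicate 2, 28S-3527 went from 1.26 to 0.80 and Um116 from 1.57 to 0.82.

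Relative to the flanks, edgeR gave 0 of 5803 positions and 561 at an unadjusted p under 0.05. The smallest p among positions with more read ends belonged to 28S-2870, 18S-1455, 28S-3527, 28S-2301 and 18S-116, and among those with fewer to 18S-510, 18S-511, 18S-264, 28S-699 and 28S-2426 (log2 fold changes of -0.52 to -0.28). The recomputed score gave 0 of 5861 positions by limma, with 303 at an unadjusted p under 0.05 and a lowest adjusted p of 0.0822 at 28S-1155, which scored 0.039 higher in the knockout, and 0.0033 higher with 2 flanking positions on each side. The next positions with a higher score were 18S-510 (0.138), 18S-1174, 28S-2789 and 5.8S-56, and those with a lower score were 18S-1208, 28S-714, 28S-765, 28S-2119 and 28S-2301 (-0.146). 28S-2301 was thus named by all 3 tests, with more read ends and a lower score in the knockout. The 3 tests use the same read-end count, so they do not back each other. Its adjusted p was 0.354 by counts, 0.503 relative to the flanks and 0.692 by limma on the recomputed score. With 1 library left out, the recomputed score gave 5 positions without control replicate 2, 4 without knockout replicate 2, 2 without knockout replicate 1, 1 without knockout replicate 3 or control replicate 1, and 0 without control replicate 3. The other tests gave 0 positions each time.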

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

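Library weights, the omission of knockout replicate 2 with control replicate 3 and adjustment over the list alone were chosen after seeing the data. Under every alternative, those included, the score at 18S-Um116 stayed lower and its read ends higher in the knockout, and no listed site passed limma (lowest adjusted p from 0.0603 to 0.736). The score difference ranged from -0.149 to -0.047 with 1 library left out. Rebuilding the score with 6 flanking positions returned the deposited values and tests nothing. The adjusted p of the count test at Um116 was 0.259 with DESeq2 and 0.327 to 0.387 with other normalizations or filters. With TMM within each rRNA, the counts at 5.8S-34 and 5.8S-50 went from -0.55 to -0.24. With both libraries left out, Um116 became a call in the count test (log2 fold change 0.80, adjusted p = 0.0489), the 1 position called by that test. It was no call in the flank test over all positions (adjusted p = 0.190).

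Without both libraries the mean score difference over all sites but Um116 was 0.000737 in place of -0.0038, and differences reversed at 18S-159 (0.00854), 18S-166 (-0.00149) and 28S-4560 (0.0116), for the 18S (0.000563), 28S (0.00129) and highly methylated sites (0.00199) and for sites without a listed neighbour (0.00208). None of these passed a threshold in either setting but the highly methylated list, which then lost its call. 18S-159 also reversed on the arcsine scale (0.000328) and with library weights (0.00229), as did 18S-166 (-0.000778) with weights. The 18S list reversed on the logit scale (0.00567) and the highly methylated list after centring (0.000337). The cause of these was not tested.

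Of the site lists, 1 passed camera. The count was 0 on the logit scale, with an estimated correlation, with fry and without both libraries. After centring it was 2, the partly and the highly methylated sites, which are near mirror images in this test. With 1 library left out it ran from 0 to 2. With 2 flanking positions, the score difference was larger in size at 28S-4020 (-0.0917) than at Um116 (-0.0873), 18S-1447 went to -0.0748 and Um121 to -0.00973. Relative to these flanks, read ends at 28S-2426 reversed (0.079), those at 18S-511 went from -0.28 to -0.016 and those at 18S-510 from -0.39 to -0.21. The recomputed score at 28S-1155 went from 0.039 to 0.0033, at 28S-714 to -0.0945 and at 28S-765 to -0.132, and the scores at 18S-510, 28S-2789 and 18S-1208 were 0, at the floor.

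With 1 library left out, the difference ran from -0.0017 to 0.0103 at 18S-99, from -0.0113 to 0.00401 at 18S-159, from -0.00112 to 0.000594 at 18S-166, from -0.0127 to 0.000466 at 5.8S-14, from -0.0756 to 0.00687 at 28S-4560, from -0.00294 to 0.0853 at 28S-3723 and from -0.00301 to 0.00163 for the highly methylated sites. Positions called by the recomputed score ran from 0 to 5. An arm left with 2 libraries rests on little spread of its own.

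The replicate numbers did not pair the libraries: deviations from the group means of same-numbered libraries correlated at -0.061, 0.021 and 0.139 for scores and -0.080, 0.185 and 0.214 for counts, and by scores 1 of the 3 knockout libraries correlated best with its own number. With the replicate number as a block, 30 positions passed the count test. The 2 lists that passed camera were the partly and the highly methylated sites, near mirror images. The flank test adjusted over the list alone passed at 4 sites (18S-116, 28S-4426, 28S-4607 and 5.8S-75). The other counts stayed at 0.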

Other observations

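The tests of explanations and the splits of the libraries reported here were chosen only after the results were seen, as were the positions described outside the fixed lists.

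The listed sites nearest the 3' end of 28S, from 28S-4560 to 28S-4607, were all lower in the knockout. These 5 sites are guided by SNORD119, SNORD91B and SNORD91A, SNORD72, SNORD78, and SNORD121B and SNORD121A. Of them, 28S-4560 and 28S-4588 also belong to the partly methylated list. 28S-4588, 28S-4590 and 28S-4593 share flanking positions, so the sites are not independent. The listed sites just before, 28S-4541 and 28S-4506, differed by -0.0076 and 0.0017. The mean score of the 5 sites was 0.753 ± 0.017 (SD, n = 3) in the knockout and 0.787 ± 0.027 (SD, n = 3) in the control, with an exact permutation p = 0.2. Without control replicate 3 the difference was -0.018 in place of -0.034, and 4 of the 5 were lower. 28S-4590 (0.873 and 0.899) and 28S-4593 (0.965 and 0.978) did not overlap between genotypes.

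Protection as strong as at listed sites also appeared outside the list. Of 5766 unlisted positions with enough flank reads, 36 scored at least 0.95 in every library with a mean flank count of at least 1000. Of these, 3 stood alone, with both neighbouring positions below a mean score of 0.8: 18S-1383 (0.995 in the control, 0.987 in the knockout), 18S-994 (0.981 and 0.983) and 28S-1747 (0.965 and 0.963). None differed between genotypes in limma, where the lowest adjusted p among the 36 was 0.895, and no explanation was tested.

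At 18S-Um116, knockout replicate 2 differed from the mean of the other 2 knockout libraries by -0.199, and its scores were lower at 70 of the other 94 sites too. The median difference over the 94 was -0.006, and 0 of them were as far below. That count decides little, since a proportional change would move the scores of well-protected sites only slightly. On the log2 scale of the remainder the target stood at 1.45, the other sites at a median of 0.23 ± 0.51 (SD over sites), and the highest of them, 28S-389, came near at 1.20. The target thus stood highest, but with that spread over sites and another site so near, these values cannot decide. A change across the whole library that varies between sites stays possible. Poisson counting error alone is argued against, since the upper end of the library's interval, 0.706, lay below 0.874, the lowest lower end of the other knockout libraries. This does not set the site apart, since over all positions the library differed from knockout replicates 1 and 3 by more than counting error (chi-square per degree of freedom 21.7 and 27.1). Fewer read ends at the flanks are argued against too. The flank count of knockout replicate 2 was 0.984 times that of the other knockout libraries and within the range of the other 5 libraries (4480 to 5218), where a ratio of 0.356 would be needed. A candidate explanation that stays open is that the knockout libraries differ in how much of the methylation guided by SNORD42A or SNORD42B is left, which was not tested because neither snoRNA was measured here.

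The real grouping gave the largest score difference at any listed site, 0.113, and the highest among the other splits of the 6 libraries was 0.0887, so 1 of the 10 splits reached it. For the 6 partly methylated sites the real difference was 0.0431 in size, the highest other 0.0417, and 1 of the 10 splits reached the real one. Camera called 1 list in the real grouping and up to 2 in another, with 2 of 10 splits as large. Sites called by limma numbered 0 in the real grouping and at most 0 in the others, as did positions by counts and by flanks, while the recomputed score gave 0 and at most 1. In each of these, 10 of 10 splits were thus as large. With 10 splits no share under 0.05 can be reached.

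The partly methylated sites were lower in the knockout at 6 of 6. A shift of all positions at that score level is argued against: 1276 unlisted positions with a mean score of 0.4 to 0.8 differed by 0.00702 on average, and 0.97% of 10000 random lists of 6 of them were as low as the list. That share measures the spread over positions and not between libraries, for which the exact permutation p was 0.1. Whether a score scale that leaves such sites more room to move accounts for part of it was not settled. On the logit scale camera's p was 0.0216 with the preset correlation but 0.153 with an estimated one. On the untransformed score these were 0.0114 and 0.124, so the loss goes with the correlation setting and does not bear on the scale. On the logit scale the list still differed more, by -0.194 against -0.0209 at the highly methylated sites, where scores were clipped at 0.99. Control replicate 3 carried part of the difference, which was -0.0277 without it, or 64.4% of its size, with 5 of 6 sites lower, and without knockout replicate 2 as well it was -0.0177 (camera adjusted p = 0.638), so that the share of these libraries and that of the genotype cannot be told apart with these libraries. A biological explanation stays open as a hypothesis that was not tested.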
